A study of Homo sapiens with 20 samples.

How the data were processed

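Expression was measured in HMVEC on 20 Affymetrix human genome arrays, 10 of type A and 10 of type B, from total RNA of which about 8 ug was made into biotinylated cRNA, per the labels. The values deposited by the authors are in the unit intensity: a MAS5 signal per probe set on a linear scale, MAS5 being named in the submitters' processing notes. The MAS5 version is not given in the sources used here. The values show that every array had been scaled to a 2% trimmed mean of about 500. Scanner files and detection calls were not used here. Array A carries 22283 probe sets and array B 22645.

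Samples were grouped by series (Matrigel or VEGF) and time, both per the labels, with 1 array per series, time and array type. Each array was rescaled to a trimmed mean of 500, leaving out 2% at each end, 50 was added, and log2 was taken. The offset shrinks differences of dim probe sets. Control probe sets, XIST and Y-linked genes were left out. Probe sets with a mean signal of at least 200 over the 10 arrays of their type were kept, and for each gene 1 probe set was used, from array A before array B and then the one with the brightest mean. Probe sets were assigned to genes through the platform annotation, with symbols updated from the NCBI gene table of assembly GRCh38.p14. On array A 19065 probe sets named 1 gene, 1043 several, 2107 none and 68 were controls, and on array B the numbers were 15426, 554, 6597 and 68. Probe sets naming several genes or none were left out.

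The comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The series were compared over 8 arrays of each type at 4 matched times with time as a block. Trends were slopes on log2 time in h over the 5 Matrigel times, and over the 4 VEGF times after 0 h. The VEGF 0 h array was compared with the mean of the later 4, and the difference in trend was the interaction of series and log2 time at the matched times. Genes at least 2-fold apart at all matched times were counted with no test. With no replicates, the residual of each fit is the variation over times or about a line. The limma p of a gene thus measures how steady a difference is over times and not how it would vary between cultures. The number of arrays limits the precision.

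There were 24 gene lists: immediate-early, VEGF response, NF-kB and inflammatory, G1/S and replication, mitosis, cell polarity, basement membrane, matrix proteolysis, integrins and adhesion, endothelial junctions, Notch with tip and stalk cells, hypoxia and glycolysis, cholesterol synthesis, endoplasmic reticulum stress, heat shock, TGF-beta with BMP and ID, YAP and cytoskeleton, interferon response, ribosomal proteins, ribosome biogenesis, endothelial markers, and markers of fibroblast and mural, leukocyte and epithelial cells. Each of the 23 with at least 3 measured genes was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. Camera compares the genes of a list with other genes, so its p does not measure variation between cultures and need not mean a difference steady over times. Fry tests whether the genes of a list move, on balance, in one direction and does not compare them with other genes. With the estimated correlation 0 lists passed in each of the 5 comparisons. That correlation was estimated from fits with 2 to 4 residual degrees of freedom, so failing to pass with it does not show that a list is unchanged. The groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined.

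Named genes in the series comparison were the 12 higher and 12 lower with the largest difference among those past the threshold with the same sign at all 4 times. For each trend and for 0 h they were the 8 of each direction with the largest value past the threshold, and for the difference in trend the 5 of each sign. Where fewer than 3 of a direction passed, the 6 with the largest moderated test statistic were named with their values. Up to 4 members of each list, by test statistic, could be named as well. Other probe sets of the named genes were read in the same way.

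The alternatives were the values as deposited, quantile normalization, offsets of 16 and 200, no signal filter and a mean of at least 500. Further ones left out probe sets with the suffix _x_at or _s_at, used limma trend, or took an adjusted p under 0.10. Others were probe sets in place of genes, each time left out in turn, linear time and Matrigel times up to 4 h. For the series comparison there was also no time block, with the matched or with all times. The tests of lists with each time left out, or up to 4 h with camera at either correlation and with fry, were chosen after seeing the data. The fits were tested on simulated data with changes planted among 11243 genes on noise of the size seen in each fit. The fold of a slope was reached over the times of that fit. The noise was drawn independently for each gene and array, and planted differences were constant over times and planted slopes exactly linear. The shares recovered hold for such changes. They need not hold for real ones, which can vary over times, or for noise shared by the genes of an array. Of planted 2-fold, 4-fold and 16-fold changes the series comparison recovered 64.3%, 94.3% and 100%, the Matrigel trend 2.86%, 52.9% and 91.7%, the VEGF trend 0%, 70% and 93.3%, the 0 h comparison 28.6%, 90% and 98.3% and the difference in trend 0%, 25.7% and 83.3%. Calls on genes with nothing planted were 7, 9, 5, 12 and 2 in the same order. Tables were handled in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.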

Results

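Gene expression was measured in HMVEC, primary human microvascular endothelial cells, on 20 oligonucleotide arrays. The cells formed 2 time series. In the Matrigel series, labelled tubulogenesis, cells attached to plates coated with Matrigel, a basement membrane extract on which endothelial cells form tube-like networks, and were collected after 0.5, 1, 2, 4 and 8 h. In the VEGF series, labelled proliferation, cells attached to gelatin-coated plates, were induced with VEGF, the main growth factor of blood vessels, and were collected after 0, 0.5, 1, 2 and 4 h. Each series and time gave 1 array of type A and 1 of type B, which share only 100 probe sets besides controls. On these the SD of 1 array's log2 value, from A against B, was 0.121, which reflects the measurement and not the culture. There were thus no replicates of a series and time, and the number of arrays limits the precision of every value. Matrigel, gelatin and VEGF differed together between the series, and the labels do not say whether both series came from the same culture. A difference between series therefore belongs to the sum of substrate, VEGF and any difference of culture. After filtering, 11243 genes were compared, 6435 read on array A and 4808 on array B. Folds are ratios of signal + 50 and levels are log2(signal + 50). A gene was kept at a mean signal of 200 or more, which is a level of 7.97. Where 1 side of a comparison lies below that level no fold is given for the gene, and its log2 difference depends on the offset of 50.

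RNA quality differed between the series. Affymetrix arrays carry probe sets for the 5' and the 3' end of beta-actin and GAPDH, and the 5'/3' ratio drops when RNA is degraded. At the 4 matched times the actin ratio on array A averaged 0.735 (SD 0.0895) in the Matrigel series and 0.957 (SD 0.113) in the VEGF series, and on array B 0.740 (SD 0.108) and 0.944 (SD 0.0466), lower in Matrigel at 4 of 4 times on both. The GAPDH ratio differed less on array A, 1.11 against 1.20, lower at 3 times and higher at 1 (difference -0.0925, SD 0.0918). On array B it was 0.977 against 1.17, lower at 4 of 4 times (difference -0.195, SD 0.0907). The Matrigel 8 h arrays stood apart, with actin ratios of 0.122 on array A and 0.129 on array B. Signals of the added control transcripts were 1.35-fold higher in Matrigel on array A and 1.43-fold higher on array B, at 4 of 4 times each. Correlations of log2 signal across probe sets, which are not independent replicates, ran from 0.957 to 0.986 between VEGF arrays of type A, from 0.934 to 0.963 between Matrigel arrays up to 4 h, and from 0.850 to 0.938 between the Matrigel 8 h array and the other arrays.

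**Figure D1:**
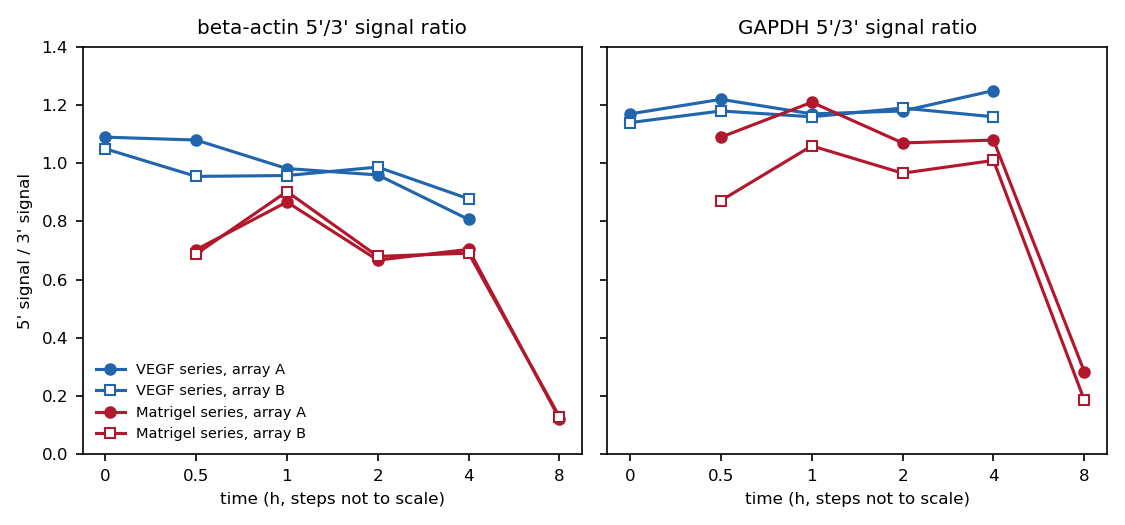
Ratio of 5' to 3' signal of beta-actin (left) and GAPDH (right) against time in h for each array, filled points array A and open points array B, coloured by series. The Matrigel 8 h arrays sit lowest, with actin ratios of 0.122 and 0.129 and GAPDH ratios of 0.284 and 0.186.

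The comparison of the series at the 4 matched times asks which genes differ between cells entering tube formation on Matrigel and cells stimulated to proliferate. ANKRD1, an ankyrin repeat protein known as a target of YAP signalling, was 6.33-fold lower in Matrigel (log2 difference -2.66, SE 0.13), with a difference between -2.51 and -2.88 at each time. LMO7, an actin-binding protein of cell junctions, was lower as well (log2 difference -2.26, with a dim level of 6.98 in Matrigel). BHLHE41, a transcriptional repressor, was 2.84-fold lower (log2 difference -1.51, and -0.63 on its other probe set). MPZL2, a cell adhesion protein of the immunoglobulin family, was higher (log2 difference 2.29, SE 0.18, and 0.91 on its other probe set), from a level of 7.79 in the VEGF series. The microfibril protein MFAP2 was 3.74-fold higher and the actin-binding protein TAGLN was higher (log2 difference 1.45, and 0.33 on its other probe set). CCBE1, a secreted protein needed for lymphatic vessel growth, was 2.56-fold higher (1.36, and 2.00 and 0.61 on others).

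In all, 41 genes passed the limma test at an adjusted p under 0.05, 16 higher and 25 lower in Matrigel, and the smallest adjusted p was 0.00307, for ANKRD1. Among the others higher in Matrigel were GBP3 (a guanylate-binding protein, 3.18-fold), the lysosomal protease CTSH (2.85-fold) and the quinone reductase NQO2 (2.19-fold). Higher as well, from dim VEGF levels, were HLA-DPA1, an MHC class II chain (log2 difference 1.77), FAM167B (1.65), the sulfotransferase CHST1 (1.57, and 0.38 on its other probe set) and the noncoding RNAs PRKAG2-AS1 (1.53) and LNCARSR (1.20). Their adjusted p values, with those of MPZL2, MFAP2, TAGLN and CCBE1, ran from 0.0166 to 0.0467. Among those lower were TMEM200A (4.12-fold), NKTR, a cyclophilin-like protein (3.89-fold, log2 difference -1.96, and -0.26 and -1.59 on others), the noncoding RNA SNHG24 (3.30-fold), ANKRD36B (log2 difference -1.55) and PDP1, the phosphatase that activates pyruvate dehydrogenase (2.83-fold, log2 difference -1.50, and -0.46 on its other probe set). CDC42, a GTPase that organises cell polarity, was 6.21-fold lower on the probe set used (adjusted p = 0.0051), but its 2 other probe sets differed by 0.24 and -0.13. BPTF, a subunit of a chromatin remodeller (log2 difference -1.92), had 3 other probe sets at 0.02, -0.16 and 0.07. SPIN1, a histone reader (-1.58), had another at 0.20, and ZBTB38, a zinc finger protein (-1.41), had others at 0.41 and -0.42. Of the 25 genes lower in Matrigel 17 had other probe sets, and the median of these, taken in the direction of the call, was 0.13. Of the 16 higher genes 5 had other probe sets, with a median of 0.78. In 3 of the 5, as in 11 of the 17, no other probe set was nearer to the called size than to 0. The lower mean level was under 7.97 for MPZL2, HLA-DPA1, FAM167B, CHST1, PRKAG2-AS1, TAGLN and LNCARSR in the VEGF series and for LMO7, SPIN1 and ANKRD36B in Matrigel, so their sizes depend on the offset. The log2 difference of LMO7 was -2.64 with an offset of 16 and -1.45 with an offset of 200, that of MPZL2 2.48 and 1.73, that of HLA-DPA1 2.11 and 1.06 and that of PRKAG2-AS1 1.90 and 0.86. The calls rest on all 4 times together: without 0.5 h 1 gene passed, without 1 h 5, without 2 h 3 and without 4 h 2, in fits with fewer arrays. The differences themselves were at least 2-fold at all 4 times for 10 of the 16 higher and 11 of the 25 lower genes. The actin 5'/3' ratio was lower in Matrigel at each of these times. The balance of directions depended on the threshold of the limma test. At an adjusted p under 0.10 there were 158 genes higher and 144 lower, and at an unadjusted p under 0.05 there were 1266 and 824.

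**Figure D2:**
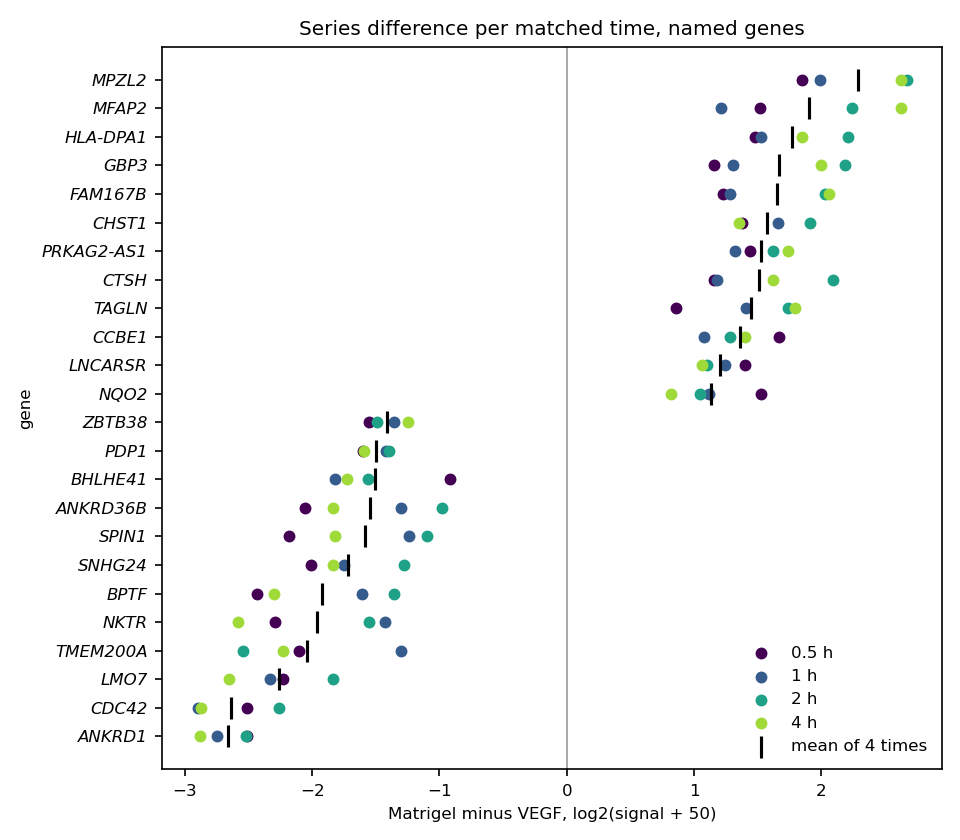
Difference in log2(signal + 50), Matrigel minus VEGF, on the horizontal axis for the 24 named genes on the vertical axis, with 1 coloured point per matched time and a bar at the mean of the 4 times. ANKRD1 lies lowest at -2.66 and MPZL2 highest at 2.29, and each gene keeps its sign at all 4 times.

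Of the 23 gene lists tested, 3 differed between the series by camera. Cholesterol synthesis genes were lower in Matrigel, 17 of 19 measured members, with a median log2 difference of -0.45 (adjusted p = 0.00068, and adjusted p = 0.582 with an estimated correlation). That difference was not steady over time. Against the VEGF 0 h array the list median in Matrigel was 0.30 at 0.5 h, -0.08 at 1 h, -0.81 at 2 h and -0.69 at 4 h. In the VEGF series it was 0.01, 0.03, 0.08 and 0.04, so the list was higher in Matrigel at 0.5 h and lower at 2 and 4 h. Values of its members included -0.70 for the isomerase IDI1 and -0.56 for the mevalonate pathway kinase PMVK, and 0 members passed the test over all genes and 0 when adjusted over the list alone. Hypoxia and glycolysis genes were higher, 23 of 28, median 0.17 (adjusted p = 0.0308, adjusted p = 0.582 with an estimated correlation), with the glucose transporter SLC2A3 at 1.00 and VEGFA at 1.13. Of these 0 passed over all genes and 1 passed adjusted over the list alone, and the call of the list ended under quantile normalization (adjusted p = 0.219). Ribosomal protein genes were higher, 28 of 28, with a median of 0.18 (adjusted p = 0.00519), a direction that turned under quantile normalization (adjusted p = 0.962). With an estimated correlation the ribosomal list had an adjusted p = 0.62, and 0 members passed over all genes or adjusted over the list alone. Each of the 3 calls ended without 2 h (adjusted p = 0.0588), the hypoxia call without 0.5 h (adjusted p = 0.0895) and the ribosomal call without 4 h (adjusted p = 0.124), and the count of lists was 5 without 0.5 h.

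The lists closest to the formation of tubes did not pass camera. Fry, which does not compare a list with other genes, gave an adjusted p = 0.0304 for basement membrane, 0.0409 for matrix proteolysis and 0.0428 for endothelial junction genes, all up. Fry also passed the endoplasmic reticulum stress list (adjusted p = 0.0428) and the hypoxia list (adjusted p = 0.0304). It did not pass the cholesterol list (adjusted p = 0.402) or the ribosomal list (adjusted p = 0.153). Of 30 measured Notch, tip and stalk cell genes 20 were higher in Matrigel (median 0.29, adjusted p = 0.181), with log2 differences of 2.87 for the Notch ligand DLL4, 2.73 for the chemokine receptor CXCR4 and 1.46 for the arterial ephrin EFNB2. The VEGF levels of DLL4 (7.28) and CXCR4 (7.20) were dim, as were those of ITGB4 (6.83) and VEGFA (7.68), and the sizes of these 4 depend on the offset. Of the Notch, tip and stalk cell genes 0 passed over all genes, and 9 higher and 2 lower passed adjusted over the list alone. Basement membrane genes had a median of 0.20 (19 of 28 higher, adjusted p = 0.0792), with COL5A1 at 1.02 and NID2 at -1.37, and 8 higher and 2 lower passed adjusted over the list alone against 0 over all genes. Of 25 measured cell polarity genes 13 were higher and 12 lower (adjusted p = 0.405), and CDC42 alone passed over all genes, against 1 higher and 2 lower adjusted over the list alone. Of 26 YAP and cytoskeleton genes TAGLN was higher and ANKRD1 lower past the test (list adjusted p = 0.436), against 2 higher and 3 lower adjusted over the list alone. Integrin and adhesion genes had a median of 0.08 (adjusted p = 0.436), with the laminin receptor chain ITGB4 at 1.79, matrix proteolysis genes 0.17 (adjusted p = 0.153), and TGF-beta, BMP and ID genes 0.16 (adjusted p = 0.194), with the matrix protein TGFBI at 1.49. Immediate-early genes had a median of 0.36 (adjusted p = 0.0884) and interferon response genes 0.20 (adjusted p = 0.29). Adjusted over the list alone 4 immediate-early genes were higher and 2 lower, 2 proteolysis genes higher and 1 lower, and 3 TGF-beta, 2 interferon and 1 integrin gene higher, against 0 of each over all genes.

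Medians of the other lists were 0.11 for G1/S and replication genes (adjusted p = 0.343), 0.11 for mitosis genes (adjusted p = 0.709), 0.14 for endothelial junction genes (adjusted p = 0.343), 0.13 for endoplasmic reticulum stress genes (adjusted p = 0.343), 0.12 for heat shock genes (adjusted p = 0.895) and 0.21 for endothelial markers (adjusted p = 0.343), of which EMCN was at -1.24. VEGF response genes had a median of 0.00 (adjusted p = 0.884), NF-kB and inflammatory genes 0.01 (adjusted p = 0.941) and ribosome biogenesis genes 0.06 (adjusted p = 0.941). Of the markers of other cell types, 6 fibroblast and mural genes had a median of 0.71 (adjusted p = 0.15), TAGLN being 1 of them, 6 epithelial genes had 0.27 (adjusted p = 0.941), with SFN 2.0-fold lower past the test, and 0 of 17 leukocyte genes passed the signal filter. Adjusted over the list alone 3 fibroblast and mural genes were higher, 2 epithelial genes were higher and 2 lower, and 1 endothelial marker was lower, against 1 fibroblast gene, 1 epithelial gene and 0 endothelial markers over all genes. In the G1/S, mitosis, junction, endoplasmic reticulum stress, heat shock, VEGF response, inflammatory and ribosome biogenesis lists 0 genes passed either way. Camera's direction was down for the VEGF response, inflammatory, cell polarity, ribosome biogenesis and epithelial lists although their medians were above 0. Their means were above 0 as well for the VEGF response, ribosome biogenesis and epithelial lists and below 0 for the inflammatory and polarity lists.

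A count of size with no test gave 25 genes at least 2-fold apart in the same direction at all 4 matched times, 11 higher in Matrigel, of which 10 also passed the limma test, and 14 lower, of which 11 did. At a given time between 457 genes (at 1 h) and 782 genes (at 4 h) were at least 2-fold apart. The count at all times became 74 without 0.5 h, 47 without 1 h and 42 without 2 h.

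The trend within the Matrigel series asks which genes change as cells settle on the matrix from 0.5 to 8 h. By camera cholesterol synthesis genes fell at an adjusted p = 1.2e-16, which became an adjusted p = 0.32 with an estimated correlation. The slope was negative in 19 of 19 measured, with a median of -0.45 log2 per doubling of time. The median over the genes of each gene's fall in log2 level was 1.06 from 0.5 h to 4 h and 1.81 from 0.5 h to 8 h. By 4 h IDI1 was 3.61-fold lower than at 0.5 h, the sterol oxidase MSMO1 2.76-fold lower, the sterol reductase DHCR7 2.22-fold lower and the fatty acid desaturase FADS2 2.45-fold lower. By 8 h, on the array with an actin 5'/3' ratio of 0.122, these were 4.91-fold, 5.02-fold, 4.22-fold and 5.86-fold lower. G1/S and replication genes fell at an adjusted p = 3.91e-08, and adjusted p = 0.39 with an estimated correlation, 28 of 29 with a negative slope and a median slope of -0.13. Against the VEGF 0 h array their median was 0.14 at 0.5 h, -0.15 at 4 h and -0.51 at 8 h, so much of the fall lies on the 8 h array. The replication helicase subunit MCM2 was 1.60-fold lower at 4 h and 2.65-fold at 8 h, and UHRF1 2.20-fold and 3.10-fold. Immediate-early genes, which are switched on within minutes of a stimulus, fell at an adjusted p = 0.000113, and adjusted p = 0.549 with an estimated correlation. The fall was in 23 of 27 with a median slope of -0.15. The level of FOS went from 10.28 at 0.5 h to 6.08 at 4 h and 6.81 at 8 h, both too dim for a fold. Matrix proteolysis genes rose at an adjusted p = 0.0216, and adjusted p = 0.39 with an estimated correlation, 19 of 26 up and 7 of 26 down, with a median slope of 0.08. ADAMTS1, a secreted matrix protease, was 8.33-fold higher at 4 h and 9.18-fold at 8 h.

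Ribosomal protein genes rose, 26 of 28 (median slope 0.07, adjusted p = 0.00271, adjusted p = 0.633 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.628). Over all genes 0 members of these lists passed, while adjusted over the list alone 16 cholesterol genes, 5 replication genes and 4 immediate-early genes were lower, 3 proteolysis genes were higher and 1 lower, and 0 ribosomal genes passed. The proteolysis call ended without 0.5 h (adjusted p = 0.146) and without 8 h (adjusted p = 0.106). The count of lists was 5 with all times, 10 without 0.5 h and 8 without 8 h. At 8 h the actin 5'/3' ratio was 0.122 on array A and 0.129 on array B. Median, mean and test differed in sign for the endothelial junction, Notch, hypoxia and heat shock lists.

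**Figure D3:**
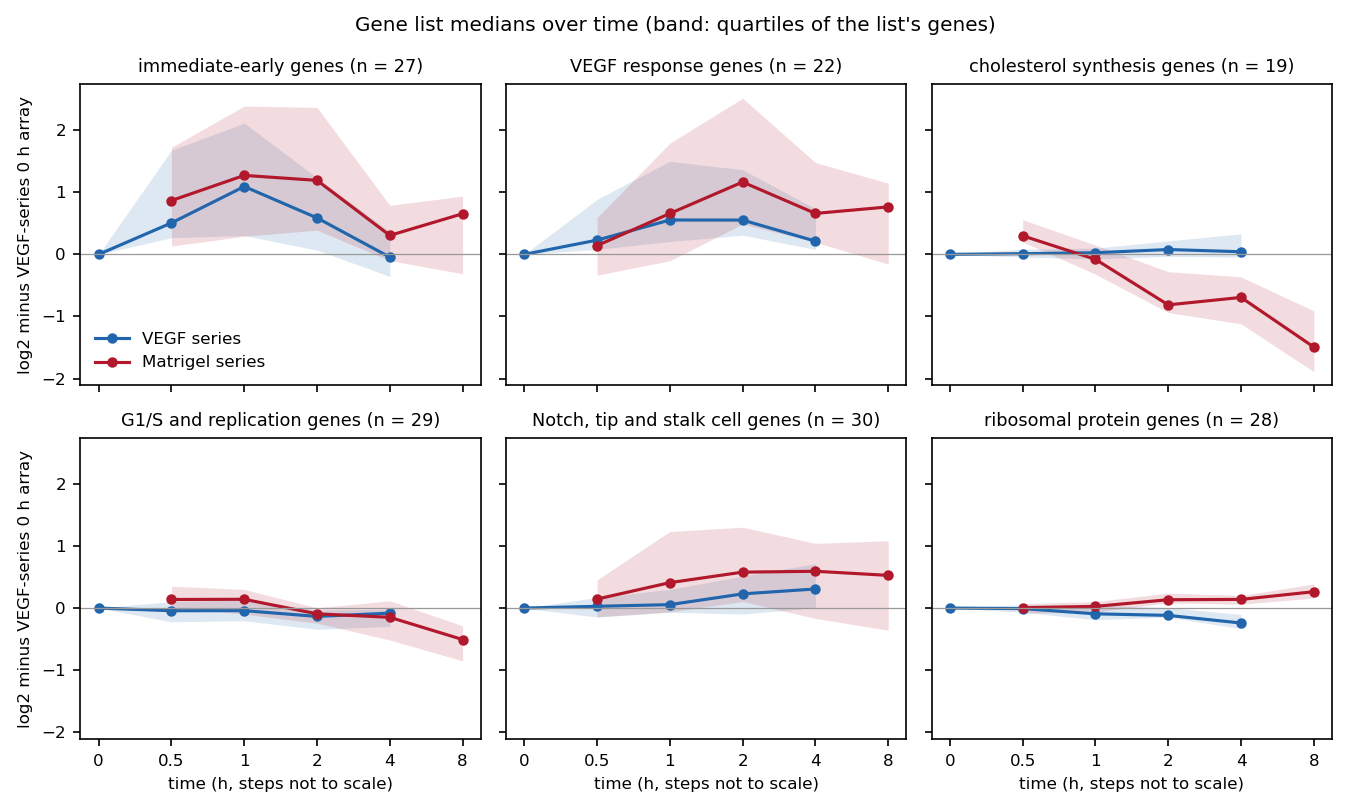
Median over the measured genes of 6 lists of log2(signal + 50) minus the value on the VEGF series 0 h array, against time in h, with bands from the lower to the upper quartile of the genes. The cholesterol synthesis median in Matrigel goes from 0.30 at 0.5 h to -1.49 at 8 h and stays between 0.00 and 0.08 in the VEGF series, and the ribosomal protein median goes to 0.26 at 8 h in Matrigel and -0.24 at 4 h with VEGF, a difference between the series that turned under quantile normalization.

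For single genes limma called 0 in the Matrigel trend, the smallest adjusted p being 0.0622, while 1582 genes had an unadjusted p under 0.05 and limma trend called 28. At an adjusted p under 0.10 there were 55. Among the genes with the largest test statistics, HHIP, an inhibitor of hedgehog signalling, was 16.6-fold lower at 4 h than at 0.5 h and APLN, the ligand of the apelin receptor, 8.43-fold lower. ABI3BP was 6.98-fold, KLF4 4.98-fold, SORBS2 4.29-fold and LINC01013 3.41-fold lower, all 6 with an adjusted p of 0.0622 over 0.5 to 8 h. At 8 h the actin ratio was 0.122 on array A, where the sizes were 8.31-fold for KLF4 and 10.5-fold for SORBS2. It was 0.129 on array B, where they were 36.1-fold for HHIP, 12.6-fold for APLN, 8.75-fold for ABI3BP and 5.26-fold for LINC01013. The slope of SORBS2 was -0.85 per doubling of time on the probe set used, but -0.81, -0.43, -0.16, -0.11 and 0.05 on its others. That of KLF4 was -0.82, and -0.34 on its other, and that of HHIP -1.40, and -0.90 and -0.89 on others. In the other direction PDK4, the kinase that shuts off pyruvate dehydrogenase, was 16.4-fold higher at 4 h and 16.6-fold at 8 h (adjusted p = 0.0636). CXCR4 was 8.77-fold and 9.67-fold higher (adjusted p = 0.0622), with a slope of 0.86 on the probe set used and 0.92 and 0.39 on others. At 4 h and 8 h SLC4A7 was 3.52-fold and 4.10-fold higher (adjusted p = 0.0655), ANTXR2 3.24-fold and 3.81-fold (adjusted p = 0.0819) and the VEGF receptor FLT1 3.04-fold and 4.62-fold (adjusted p = 0.0836). The level of DIRAS3 went from a dim 7.48 at 0.5 h to 9.67 at 4 h and 10.02 at 8 h (adjusted p = 0.0636). With 1 array per time these values stand without replicate error, and without 1 h 1 gene was called.

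**Figure D4:**
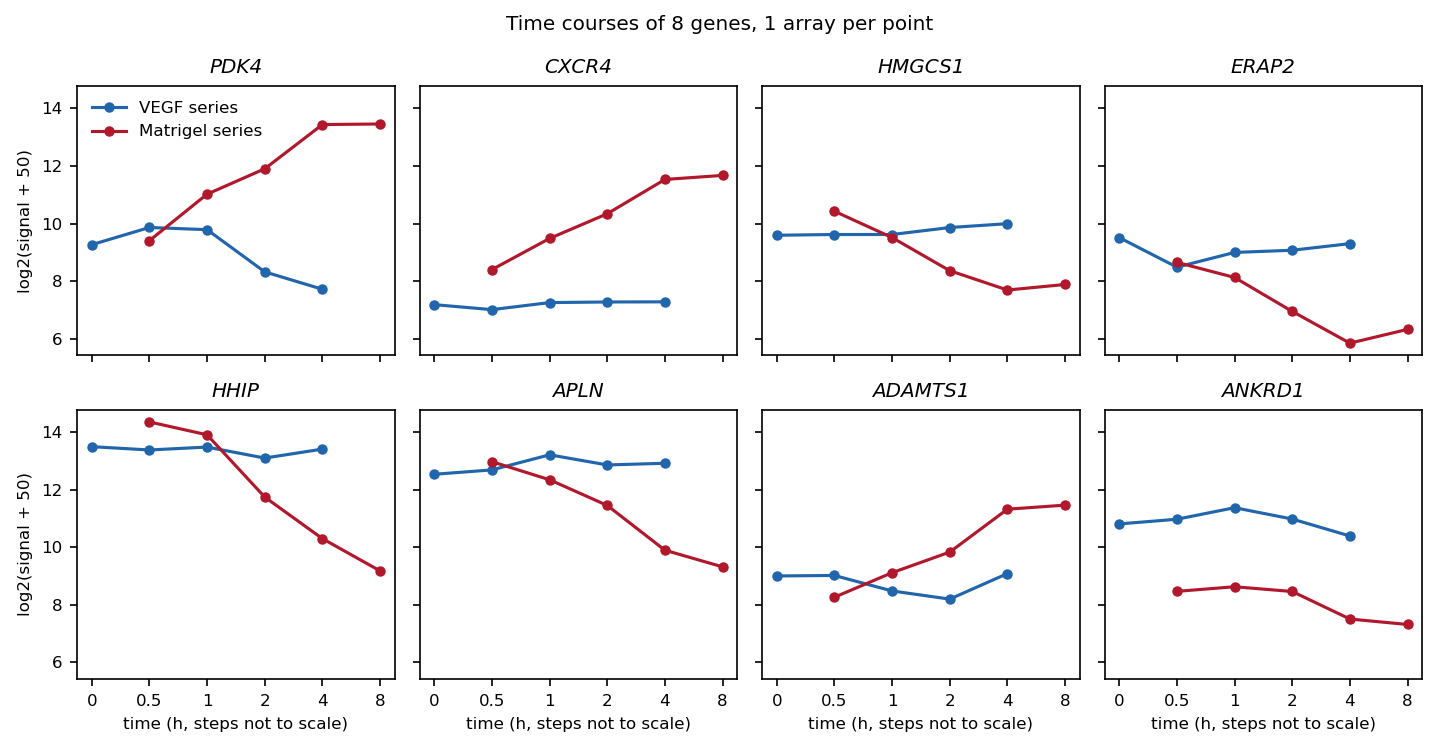
Level of 8 genes as log2(signal + 50) against time in h, 1 array per point, coloured by series. PDK4 goes from 9.41 at 0.5 h to 13.46 at 8 h in Matrigel and from 9.86 at 0.5 h to 7.72 at 4 h with VEGF, and HHIP goes from 14.35 to 9.18 in Matrigel.

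The trend within the VEGF series asks which genes change from 0.5 to 4 h of the proliferative stimulus. Over these times the actin 5'/3' ratio went from 1.08 to 0.807 on array A and from 0.955 to 0.878 on array B. The GAPDH ratio went from 1.22 to 1.25 and from 1.18 to 1.16. An effect of RNA quality on this trend was not tested. By camera immediate-early genes fell at an adjusted p = 2.83e-08, which became an adjusted p = 0.805 with an estimated correlation, 25 of 27 with a negative slope and a median slope of -0.21 per doubling of time. ATF3 was 4.30-fold lower at 4 h than at 0.5 h, and the level of FOS went from 11.37 to 5.93, too dim for a fold. Genes of TGF-beta, BMP and ID signalling rose at an adjusted p = 0.00503, and adjusted p = 0.805 with an estimated correlation, 19 of 24 with a median slope of 0.10, the signalling inhibitor SMAD6 being 4.57-fold higher and PMEPA1 3.59-fold higher at 4 h. Notch, tip and stalk cell genes rose at an adjusted p = 0.0165, and adjusted p = 0.805 with an estimated correlation, 20 of 30 up and 10 of 30 down. Their median slope was 0.05. The level of the Notch target HEY2 went from a dim 7.51 at 0.5 h to 9.91 at 4 h and that of LFNG, which glycosylates Notch, from 7.75 to 9.99. Ribosomal protein genes fell at an adjusted p = 0.0026, and adjusted p = 0.805 with an estimated correlation, 25 of 28 with a median slope of -0.07, a direction that turned under quantile normalization (adjusted p = 0.699).

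Adjusted over the list alone 7 immediate-early genes were lower, 4 TGF-beta genes higher and 1 lower, 7 Notch genes higher and 0 ribosomal genes moved, against 0 of each over all genes. The immediate-early call ended without 4 h (adjusted p = 0.4), the Notch call without 0.5 h (adjusted p = 0.284), and the ribosomal call without 0.5 h (adjusted p = 0.051) and without 4 h (adjusted p = 0.396). Median, mean and test differed in sign for the VEGF response, inflammatory, hypoxia, heat shock, fibroblast and epithelial lists. For single genes limma called 0 and limma trend called 0, with 1107 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.412, which was shared by HEY2, PMEPA1 and ATF3. At the same adjusted p UBE2QL1 (6.58-fold) and CXXC5 (3.94-fold) were higher at 4 h than at 0.5 h and KLC4 (3.46-fold) and ERICH6 (3.28-fold) lower. Levels with a dim side went from 6.71 to 8.64 for NPTX1, from 7.86 to 9.24 for PCDH1, from 9.14 to 7.26 for IFIT2, from 8.66 to 7.21 for SPATA33 and from 8.76 to 7.14 for ABHD17B. The slope of ABHD17B was -0.51 on the probe set used but -0.15 and 0.09 on its others. Other probe sets of HEY2 (0.82), PMEPA1 (0.79) and CXXC5 (0.59 and 0.75) rose as those used did.

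The 0 h array of the VEGF series, set against the 4 later arrays, asks how cells at the start of that series differ from those after 0.5 to 4 h on gelatin with VEGF. The 0 h side is 1 array of each type, so its own spread was not measured and was assumed to be that of the later arrays, on which every value below rests. By camera VEGF response genes were lower at 0 h at an adjusted p = 6.42e-06, which became an adjusted p = 0.648 with an estimated correlation, 20 of 22 with a median log2 difference of -0.36. The chemokine CXCL8 was 2.55-fold lower. The prostaglandin synthase PTGS2 had a level of 7.62 at 0 h and a mean of 10.38 later, and tissue factor F3 6.34 and 8.72, both too dim at 0 h for a fold. Inflammatory NF-kB genes were lower at 0 h at an adjusted p = 0.0016, and adjusted p = 0.648 with an estimated correlation, 10 of 13 with a median of -0.28. Immediate-early genes were lower at an adjusted p = 0.00158, and adjusted p = 0.7 with an estimated correlation, 21 of 27 with a median of -0.62, the nuclear receptor NR4A1 having levels of 7.15 and 8.55. TGF-beta, BMP and ID genes were lower at an adjusted p = 0.0035, and adjusted p = 0.648 with an estimated correlation, 21 of 24 with a median of -0.28, SMAD7 having levels of 7.01 and 9.47. Mitosis genes were higher at 0 h at an adjusted p = 0.011, and adjusted p = 0.7 with an estimated correlation, 28 of 32 with a median of 0.15 and NEK2 at 0.51.

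Adjusted over the list alone 3 VEGF response genes and 1 inflammatory gene were lower at 0 h and 0 genes of the other lists passed, against 0 of each over all genes. That inflammatory gene was CXCL8, which is in the VEGF response list too and is also 1 of its 3 genes. NR4A1 is in both the immediate-early and the VEGF response list, so the calls of these lists are not separate findings. The mitosis call ended without 2 h (adjusted p = 0.122) and with no filter on dim probe sets (adjusted p = 0.0578), as did the TGF-beta call with no filter (adjusted p = 0.0578). Median, mean and test differed in sign for the proteolysis, endoplasmic reticulum stress and endothelial marker lists. For single genes limma called 0 and limma trend 0, with 1036 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.114. Signals at 0 h were 2.85-fold higher for CCDC163, 2.15-fold for CBLN2, 2.10-fold for PIK3C2B and 2.15-fold for GABRQ. The other genes named by their test statistic had a side under 7.97, and their log2 differences depend on the offset. These were 2.29 for CDK15 and 2.14 for NXF3, dim at the later times, and -1.74 for MIR1915HG, -1.95 for ZSCAN18, -1.45 for P2RX5, -1.88 for VPS53, -1.43 for GRIPAP1 and -2.37 for SNRNP48, dim at 0 h. The other probe sets of VPS53 differed by only -0.21 and -0.22.

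The difference in trend asks which genes take another course on Matrigel than with VEGF over 0.5 to 4 h. PDK4 had a slope of 1.30 log2 per doubling of time in Matrigel and -0.79 in the VEGF series, a difference of 2.09 (SE 0.17, adjusted p = 0.0445). CXCR4 had slopes of 1.03 and 0.08, a difference of 0.94 (SE 0.09, adjusted p = 0.0492). HMGCS1, which makes the precursor of mevalonate in cholesterol synthesis, had slopes of -0.94 and 0.14, a difference of -1.07 (SE 0.09, adjusted p = 0.0445). ERAP2, an aminopeptidase that trims antigenic peptides, had slopes of -0.96 and 0.25, a difference of -1.21 (SE 0.12, adjusted p = 0.0492). Each of the 4 had a level under 7.97 at 1 or more times, the lowest being 7.72 for PDK4, 7.01 for CXCR4, 7.69 for HMGCS1 and 5.85 for ERAP2. With an offset of 16 the differences were 2.18, 0.96, -1.15 and -1.61, and with an offset of 200 they were 1.80, 0.84, -0.83 and -0.68.

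These 4 genes were those called by limma for a difference in trend, 2 with a higher and 2 with a lower slope in Matrigel, and 0 genes were called without 0.5 h, without 1 h, without 2 h or without 4 h. Values short of the test included slope differences of -1.29 for the vasoconstrictor EDN1, -1.02 for HDAC9, -0.94 for NPTX2, -0.82 for PLA2G4C, 0.88 for IFIT2, 0.87 for the collagen chain COL6A3, 0.73 for MELTF and 0.65 for ABTB3, with adjusted p between 0.0689 and 0.0958, of which IFIT2, COL6A3, NPTX2 and HDAC9 had a level under 7.97 at 1 or more times. Cholesterol synthesis genes had the lower slope in Matrigel in 19 of 19, with a median difference of -0.44 (adjusted p = 8.22e-12, adjusted p = 0.308 with an estimated correlation), HMGCS1 passing over all genes and 9 members adjusted over the list alone. Mitosis genes had the lower slope in 28 of 32, median -0.17 (adjusted p = 0.000291, adjusted p = 0.785 with an estimated correlation), a direction that turned without 4 h (adjusted p = 0.254). Ribosomal protein genes had the higher slope in 27 of 28, median 0.11 (adjusted p = 5.72e-05, adjusted p = 0.636 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.856).

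Endothelial markers had the higher slope in Matrigel in 18 of 26, with a median difference of 0.07 and the lymphatic receptor LYVE1 at 0.78 (adjusted p = 0.0192, adjusted p = 0.308 with an estimated correlation). Fibroblast and mural markers had it in 5 of 6, median 0.21 (adjusted p = 0.0192, adjusted p = 0.308 with an estimated correlation). VEGF response genes had it in 16 of 22, median 0.24 (adjusted p = 0.0412, adjusted p = 0.908 with an estimated correlation), with ADAMTS1 at 1.00, STC1 at 1.06 and APLN at -1.05. Adjusted over the list alone 1 fibroblast gene and 4 VEGF response genes had a higher and 1 VEGF response gene a lower slope, and 0 endothelial markers, mitosis genes or ribosomal genes passed, against 0 of each of these lists over all genes. The endothelial call ended without 0.5 h (adjusted p = 0.277), the fibroblast call without 0.5 h (adjusted p = 0.0639) and without 4 h (adjusted p = 0.231), and the VEGF response call without 0.5 h (adjusted p = 0.882) and without 2 h (adjusted p = 0.116). With no filter on dim probe sets the fibroblast list (adjusted p = 0.168) and the VEGF response list (adjusted p = 0.12) did not pass. Median, mean and test differed in sign for the integrin, junction, Notch, endoplasmic reticulum stress, heat shock, YAP, ribosome biogenesis and epithelial lists.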

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

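The tests of other splits and orders of the arrays, of RNA integrity, of culture, of the 8 h array, of the actin ratio and of the other CDC42 probe sets were chosen after the results they bear on had been seen, while the list of intron-containing nuclear transcripts was written before its test. All 35 splits of the 8 arrays at matched times, of which the time block allows 32, were counted first. Most of them put both arrays of some time into the same group, which the real split never does, so the 8 splits with 1 array of each time in each group are used below. Over all splits that could be fitted 1 of 32 called as many genes between the series and 1 of 35 for the difference in trend, and 19 of 32 and 7 of 35 as many lists.

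The steady difference between the series covered 41 genes, and of the 8 splits of the arrays that put 1 array of each time in each group, 1 (the real one) called as many, the highest other calling 0, but 8 splits are too few for a share under 0.05. A different recovery of nuclear, intron-containing RNA did not show as a shift of 38 measured transcripts of that kind. Their median difference was 0.022 (SD 0.32), with 19 higher and 19 lower. Whether the probe sets of the 38 transcripts read their introns was not checked, so the list argues only against a shift of such transcripts as a group. The 25 genes lower in Matrigel, which were chosen by their difference, had a median of -1.32. RNA integrity stays open for these 25 genes. From 4 h to 8 h in Matrigel the actin 5'/3' ratio fell from 0.704 to 0.122 on array A and from 0.691 to 0.129 on array B. Over that step these genes changed by a median of -0.46, 19 of 25 falling. Random genes of like signal had a central range of -0.18 to 0.26. The 16 higher genes fell as well, by a median of -0.59 (central range of random genes -0.21 to 0.36, 9 of 16 falling). Genes called in either direction fell, so this change does not track the direction of the series difference. The 4 h array entered the choice of both groups, which by itself favours a fall of the higher genes and a rise of the lower ones. The groups therefore cannot be weighed against each other, and the change does not single out integrity as a cause or discount it. With 1 array as the yardstick and 4 h used in the selection, an effect of integrity cannot be told apart for either group. Another culture or lot of cells in each series cannot be told apart from the substrate or VEGF either, as each series and time has 1 array of each type, and the substrate and VEGF themselves remain open and untested.

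The cholesterol synthesis list fell in Matrigel, 19 of 19 genes (camera adjusted p = 1.2e-16, adjusted p = 0.32 with an estimated correlation). The 8 h array is not the whole cause, since over 0.5 to 4 h 19 of 19 genes had falling slopes (median -0.40, camera adjusted p = 6.19e-11), although that call too was lost with an estimated correlation (adjusted p = 0.532) and with fry (adjusted p = 0.175). From 0.5 h to 4 h the list fell by a median of 1.06 on the log2 scale. The actin ratio on array A moved by 0.001 (SD over times 0.0895), so there was no net fall of that ratio. In between, however, the ratio was 0.867 at 1 h and 0.667 at 2 h. Over that step the list median against the VEGF 0 h array went from -0.08 to -0.81. The end points of 1 control transcript therefore cannot exclude an effect of RNA integrity. Of the 60 orders of the 5 Matrigel arrays 1, the real one, gave any of the 23 lists a median slope as large (size 0.452, highest other 0.436), which argues against a chance order, though narrowly and in a test chosen after the fall was seen. Against the VEGF series 2 of the 8 splits with 1 array of each time in each group gave a median difference in slope as large (size 0.438, highest other 0.478), too few splits for a share under 0.05, as did 2 of all 35. A biological response of sterol synthesis to Matrigel stays open as a hypothesis, as does a change of the culture with time.

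CDC42 had a log2 difference of -2.63 on 1 probe set, lower in Matrigel at 4 of 4 times. The other 2 probe sets had a mean difference of 0.055, which is consistent with a change of what that probe set reads, such as 1 transcript form or the quality of its target stretch, and not of the whole CDC42 transcript pool. Among the 25 genes lower in Matrigel 17 had other probe sets, and 11 of these had none nearer to the called size than to 0 in the called direction, as had 3 of the 5 higher genes with other probe sets. A biological change of 1 transcript form was not tested and stays open.

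The Matrigel 8 h arrays had 5'/3' ratios far below the other Matrigel arrays, 0.122 (actin) and 0.284 (GAPDH) on array A and 0.129 and 0.186 on array B. These were 4 of 12 groups of 5 arrays tested for a distant array, where chance gives about 1 in 20, but all 4 read the same time point and are not independent. Slopes that differed between the series by the test of the difference itself were those of PDK4 (2.09), CXCR4 (0.94), HMGCS1 (-1.07) and ERAP2 (-1.21). Of the 8 splits with 1 array of each time in each group 1, the real one, called as many genes for a difference in trend (real count 4, highest other 0), which are too few splits for a share under 0.05, and the count was 0 with any time left out. Lists whose slopes differed between the series were cholesterol synthesis (camera adjusted p = 8.22e-12), ribosomal proteins (adjusted p = 5.72e-05), mitosis (adjusted p = 0.000291), endothelial markers (adjusted p = 0.0192), fibroblast and mural markers (adjusted p = 0.0192) and VEGF response (adjusted p = 0.0412). With an estimated correlation none of the 6 held, the adjusted p being 0.308, 0.636, 0.785, 0.308, 0.308 and 0.908 in that order, and the ribosomal call ended under quantile normalization (adjusted p = 0.856) while the mitosis direction turned without 4 h (adjusted p = 0.254). Of the same 8 splits 2 called at least the 6 lists of the difference in trend (highest other 6) and 5 at least the 3 lists of the series comparison (highest other 7), again too few splits for a share under 0.05.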

How the results depend on the processing

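The list tests with a time left out, or up to 4 h with each list test, were chosen after seeing the data. The 0 genes called in the VEGF trend and at 0 h stayed 0 under every alternative run. With the values as deposited all counts held, and under quantile normalization the series count was 35. The other counts moved, and the cause was not tested except that fewer arrays or genes enter by construction where times, arrays or dim probe sets are left out. The series count of 41 became 22 with an offset of 16, 150 with 200, 3 with no filter, 143 with a mean of at least 500, 161 with limma trend, 302 at an adjusted p under 0.10, 472 and 127 for probe sets of array A and array B, 188 with no time block and 455 with all 5 times and no block, and 1 to 5 with a time left out. The Matrigel trend count of 0 became 23 with an offset of 200, 79 with a mean of at least 500, 28 with limma trend, 55 at an adjusted p under 0.10 and 0 to 1 with a time left out. The 4 genes of the difference in trend became 2 with an offset of 16, 8 with 200, 23 with a mean of at least 500, 17 with limma trend, 15 at an adjusted p under 0.10, 9 for probe sets of array A, and 0 for array B, under quantile normalization, with no filter, with linear time and with any time left out (0 to 0). The 25 genes 2-fold apart became 11 with an offset of 200, 16 with a mean of at least 500 and 36 to 74 with a time left out.

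The counts of lists (3, 5, 4, 5 and 6 for the series, the Matrigel trend, the VEGF trend, 0 h and the difference in trend) became 0 in all 5 with an estimated correlation and 5, 1, 0, 1 and 3 with fry. Under quantile normalization the series count of lists became 1. With a time left out the series count ran from 0 to 5 and the Matrigel count from 5 to 10, being 8 up to 4 h, and 0 up to 4 h with an estimated correlation or with fry. The ribosomal list turned under quantile normalization in the series comparison (adjusted p = 0.962) and the VEGF trend (adjusted p = 0.699), and the mitosis list turned in the difference in trend without 4 h (adjusted p = 0.254, the range with a time left out being 3.88e-08 to 0.254). Of the 24 named genes of the series comparison, 60 of 72 values under another scaling or offset kept their side of the threshold and 12 lost it, and with a time left out 9 of 96 kept it and 87 lost it. Arrays resolve a gene only above background: between 43.4% and 47.8% of probe sets on array A and between 53.1% and 60.1% on array B reached a signal of 200, and the counts with another offset or filter show how far the dim genes decide them.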

Other observations

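The tests of FOXO target genes at the matched times and of the other splits were chosen after the trend of these genes had been seen, while the trend tests of LXR, FOXO and PPAR genes were written before their results.

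Metabolic and survival genes controlled by FOXO transcription factors, which are switched off by growth factor signalling, had a median log2 difference of 0.34 between Matrigel and VEGF at the matched times, with 20 of 23 measured members above 0 (PDK4 not among them). The adjusted p was 0.00293 by camera over the 4 added lists and adjusted p = 0.35 with an estimated correlation, and 1 of the 8 splits with 1 array of each time in each group, the real one, gave a median as large (highest other 0.194), too few splits for a share under 0.05, while over all 32 splits that the time block allows 3 did (highest other 0.364). Random lists of like signal had a central range of -0.07 to 0.19. Values were 1.09 for the insulin receptor INSR, 0.76 for the death ligand TNFSF10, 0.75 for TRIB1, 0.74 for the insulin receptor substrate IRS2, 0.71 for BCL6 and 0.67 for SESN3. Over the VEGF times the same list had a median slope of -0.07 per doubling of time (adjusted p = 0.0212, adjusted p = 0.212 with an estimated correlation), 16 of 23 lower.

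That FOXO targets are higher together in the Matrigel series is thus a hypothesis. The actin 5'/3' ratio was lower in Matrigel at 4 of 4 matched times on both array types, and an effect of RNA quality on the FOXO list was not tested. The list was tested because of PDK4, whose slope in Matrigel may reflect FOXO or PPAR activity, but over 0.5 to 8 h in Matrigel the FOXO list had a median slope of 0.008 (12 of 23 higher) and a list of 15 PPAR and fatty acid oxidation genes 0.07 (10 of 15 higher, adjusted p = 0.268). For the difference in trend, in which PDK4 was called, 17 of 23 FOXO genes had the higher slope in Matrigel, with a median difference of 0.11 (adjusted p = 0.0452, adjusted p = 0.196 with an estimated correlation, central range of random lists -0.10 to 0.07). Part of that difference lies in the fall of the list over the VEGF times. Members went both ways in either list, so neither hypothesis is decided.

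A fall of cholesterol synthesis genes could come from cells loaded with sterol, which would raise the targets of the sterol sensor LXR. The 9 measured LXR targets had a median slope of 0.101 in Matrigel, 7 of 9 higher (adjusted p = 0.139), which does not decide the question with so few genes. In the VEGF series, where cholesterol genes had a median slope of 0.02, LXR targets had a median slope of 0.09, 7 of 9 higher (adjusted p = 0.0641).

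The list of intron-containing nuclear transcripts rose over the VEGF times, 28 of 38 higher with a median slope of 0.06 (camera adjusted p = 0.0114, adjusted p = 0.212 with an estimated correlation), and in the Matrigel series 26 of 38 were higher, with a median slope of 0.07 (adjusted p = 0.0578).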
